A study of Drosophila melanogaster with 9 samples.

How the data were processed

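Brain RNA of 9 Drosophila samples was sequenced, 3 each from w1118 controls, FUS_WT and FUS_R521C flies on day 8 of adult life, all on food with RU486. Per the labels, RNA was extracted with TRIzol, and libraries were made with a Lexogen SENSE kit and sequenced on an Ion Torrent Proton. The deposited table holds counts per gene for each library, which the authors made by alignment and counting. The submitters' processing notes name FastQC, STAR 2.5.1, featureCounts and DESeq2. They name mm10, a mouse build, as the genome, whereas the gene identifiers are those of Drosophila, and 17490 of the 17626 genes matched to the fly annotation BDGP6.54 have the same span in it. The remaining 127 of the 17753 genes have no symbol there. The notes used here do not give the strand setting of the counting, so a gene that overlaps another on the opposite strand may hold reads of it. The human FUS transgene is not in the table and was not analysed. The labels do not describe the driver or transgene status of the control beyond its name. The kit is not stated to use molecular identifiers, so limits from counts cover counting error only.

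Library totals ran from 14413751 to 16819328 counts, so 0 counts in a library bounds a gene below 0.178 to 0.208 CPM at 95% confidence. Genes were kept with edgeR's filterByExpr at a minimum count of 10, which left 10118. Libraries were scaled with TMM (factors 0.880 to 1.10), CPM in the text uses the scaled library sizes, and a quasi-likelihood model with robust dispersions was fitted to all 9 libraries with 1 mean per group (edgeR 4.0.16, limma 3.58.1 and R 4.3.3; biological coefficient of variation 0.354, 6 residual and 12.8 prior degrees of freedom). Each of the 3 comparisons was tested as a contrast, p-values were adjusted by Benjamini and Hochberg over the genes tested, and 0.05 was the threshold. A fold against a group at 0 was computed against a floor of 3 counts over that group.

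Gene lists (35, with 4 entries that matched no gene) were tested with camera at a preset correlation of 0.01 on log2 CPM with a prior count of 3. The family of 105 list tests was adjusted together. The correlation within lists was also estimated from the data, and fry was run. With the estimated correlation 0 lists passed in any comparison, while fry called 4, 12 and 12 lists for FUS_WT against control, FUS_R521C against control and FUS_R521C against FUS_WT. Counts adjusted over the list alone used the edgeR p-values of the members.

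The groups, comparisons, gene lists, most alternatives and the rule for naming genes were fixed before the data were examined. The rule takes, per comparison, the 10 genes with the largest fold change each way among those called, with groups that do not overlap and a mean of at least 5 CPM over the 6 libraries, the up to 4 called members of each list with the smallest p, and Rm62, caz and w. It gave 329 entries, of which 323 were called. The text names part of these, picked mostly because their calls held under every alternative, so the named genes are steadier than the set: 93 of the 323 lost their call under at least 1 alternative, 77 when 1 library was left out, and 0 reversed. Of the named entries, 30 lie outside the rule and were chosen after their values were seen: the 6 genes that went opposite ways, Ilp2 and mt:CoIII in FUS_R521C against control, and others in the closing section, such as further mitochondrial genes. Of the 101 named genes 47 overlap another annotated gene, 14 of them on the same strand.

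The alternatives were DESeq2's size factors, upper-quartile scaling or no scaling beyond library size, no filter or a strict filter (10 CPM in 3 libraries), DESeq2 1.42.0, limma-voom with or without quality weights, fits of the 6 libraries of a comparison, non-robust dispersions, a replicate block, a minimum fold of 1.2, and leaving out each library. An offset for gene length per library and leaving out all 3 replicate 3 libraries, which hold digestive enzyme transcripts, were added after the data were seen. The steps were tested on simulated data: at 2-fold 46%, 48% and 36% of changed genes were recovered in the 3 comparisons, at 4-fold 84%, 82% and 88%, and a shifted list was called with 0 of 34 unchanged lists. Only 50 genes were changed at each fold, so recovery may differ where many genes change. Genes were simulated independently and these lists were drawn at random, so this does not test false calls in lists of correlated genes.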

Results

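Transcripts were sequenced from samples of adult Drosophila melanogaster on day 8 of adult life, with brain as the tissue per the labels. Flies of all groups were on food with RU486, the steroid that activates GeneSwitch drivers. The 9 libraries fall into 3 groups of 3: a w1118 control, flies heterozygous for wild-type FUS (FUS_WT), and flies heterozygous for FUS with the R521C substitution (FUS_R521C), a change in the C terminus of the protein linked to amyotrophic lateral sclerosis (ALS). FUS is an RNA-binding protein. The deposited counts sum to between 14413751 and 16819328 per library, so a gene with no count in a library lies below about 0.178 to 0.208 CPM (counts scaled to library size), a limit set by counting error only. Of 17753 genes listed, 10118 passed the filter on low counts and were tested. Levels below are CPM as mean ± SD over the n = 3 libraries of a group, log2 fold changes are given ± SE, and adjusted p-values come from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Positions are those of the deposited table. P-values measure only the spread between these libraries, which may be technical, since the labels do not say whether the libraries came from separate pools of flies.

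Replicates of 1 group correlated at r = 0.927 to 0.972 across genes (log2 CPM), and no pair agreed within sampling noise. The first principal component, with 29.0% of the variance, ordered the groups from control through FUS_WT to FUS_R521C, and the next ones held 21.7% and 15.1%. Transcripts of digestive enzymes such as the Jonah serine proteases, which the gut makes, summed to 2159 CPM in control replicate 3, 6157 in FUS_WT replicate 3 and 994 in FUS_R521C replicate 3, against 7.98 to 230 CPM in the other 6 libraries. Antimicrobial peptide transcripts summed to 2404 CPM in FUS_WT replicate 3 and to 99.2 and 198 CPM in the other FUS_WT libraries. They summed to 154 to 253 CPM in control and 605 to 654 CPM in FUS_R521C. Photoreceptor and fat body transcripts were abundant in all 9 libraries: the opsin ninaE lay between 29306 and 50570 CPM and the yolk protein gene Yp1 between 10755 and 24413 CPM. Eye and fat body make these transcripts, and the labels do not say whether such tissue was included with the brain, so changes in photoreceptor, fat body, hemocyte and chemoreceptor genes cannot be assigned to brain cells. Counts also varied with gene length between libraries. Among the 5059 more highly expressed genes, the correlation of a library's deviation from the gene mean with log2 gene length was 0.45, 0.24 and 0.07 in control replicates 1 to 3, 0.40, 0.28 and -0.06 in FUS_WT, and -0.57, -0.08 and -0.34 in FUS_R521C, with FUS_R521C replicate 2 close to FUS_WT replicate 3.

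**Figure D1:**
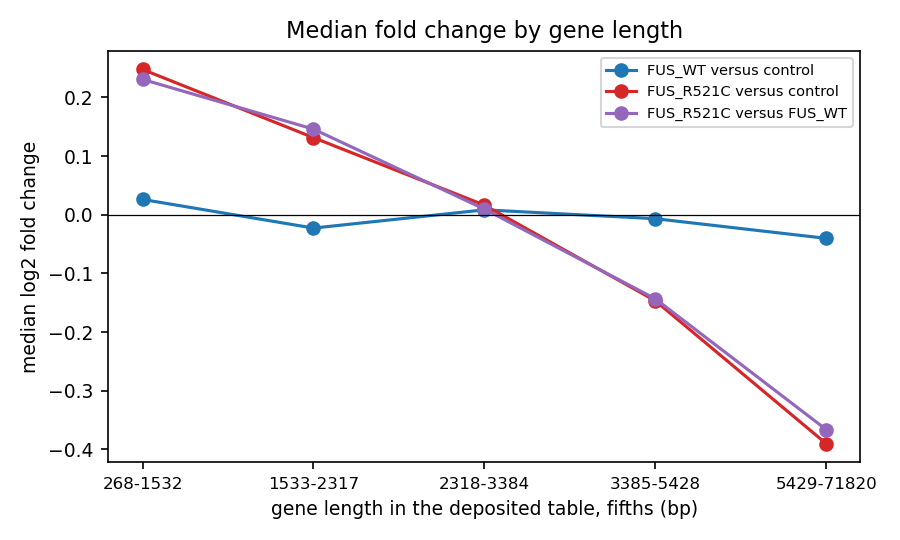
Median log2 fold change (y axis) of the 5059 more highly expressed genes in 5 classes of gene length (x axis, bp), with 1 line per comparison. FUS_R521C against control runs from 0.25 in the shortest class to -0.39 in the longest, and FUS_WT against control stays between -0.04 and 0.03.

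The series title names DDX17, an RNA helicase, as a modifier of FUS toxicity with a role in DNA repair. Its fly ortholog Rm62 (FBgn0003261, 3R, 6000426 to 6008579) was at 587 ± 21.2 CPM in control, 602 ± 53.8 in FUS_WT and 460 ± 49.6 in FUS_R521C (SD, n = 3). The log2 fold changes of Rm62 were 0.04 ± 0.14 for FUS_WT against control (adjusted p = 0.95), -0.35 ± 0.14 for FUS_R521C against control (adjusted p = 0.079) and -0.39 ± 0.14 for FUS_R521C against FUS_WT (adjusted p = 0.068). The last 2 passed with no scaling beyond library size (adjusted p = 0.0094 and 0.014) and in DESeq2 (0.026 and 0.019), and the last also without FUS_WT replicate 3 (0.047). With no scaling beyond library size the median of all genes also moved, to -0.21 and -0.18 in these comparisons. Rm62 is 5386 bp long, and the more highly expressed genes of 3385 to 5428 bp had medians of -0.15 and -0.14. It lies near the upper edge of that class, and the next class, from 5429 bp, had medians of -0.39 and -0.37. The sign of the first turned without FUS_WT replicate 1 (-0.02) and, at a value near 0, with no scaling beyond library size. Caz (caz, FBgn0285954, X, 16288810 to 16293520), the fly ortholog of FUS, fell from 60.0 ± 19.9 CPM in control to 25.7 ± 2.02 in FUS_R521C (log2 fold change -1.22 ± 0.22, adjusted p = 0.00054). Its change in FUS_WT did not pass (-0.78 ± 0.22, adjusted p = 0.061, and 0.028 without control replicate 1), and neither did FUS_R521C against FUS_WT (-0.44 ± 0.22, adjusted p = 0.18, and 0.040 with an offset for gene length). The eye pigment transporter gene white (w, FBgn0003996, X, 2790599 to 2796466), which many transgenes carry as a marker, was at 60.3 ± 3.94 CPM in control, 99.1 ± 12.0 in FUS_WT and 71.8 ± 9.94 in FUS_R521C. The w1118 allele of the control is a deletion in this gene, and w overlaps 1 gene on the opposite strand. The source of the reads of w in control was not tested. White was higher in FUS_WT than in control (0.72 ± 0.15, adjusted p = 0.0091), a call lost without control replicate 1 (0.050), control replicate 2 (0.060) or FUS_WT replicate 2 (0.052). Values of 0.25 ± 0.15 (adjusted p = 0.24) for w in FUS_R521C against control and -0.46 ± 0.15 (0.038) against FUS_WT complete the comparison. The latter did not pass without control replicate 2 (0.061), FUS_WT replicate 1 (0.16), FUS_WT replicate 2 (0.11), FUS_R521C replicate 1 (0.11) or FUS_R521C replicate 2 (0.10), nor in a fit of only the 6 libraries compared (0.075), with a replicate block (0.054) or at a minimum fold of 1.2 (0.16).

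FUS_WT against control compares flies with extra wild-type FUS to the control, and line and FUS are confounded in it. Of 30 neuropeptide genes 10 fell, 0 rose and 20 did not pass (list adjusted p = 2.3e-09, and adjusted p = 0.42 with an estimated correlation). Ilp2 (FBgn0036046, 3L, 9799698 to 9800440), an insulin-like peptide of the median neurosecretory cells, fell from 61.1 ± 8.67 CPM to 1.59 ± 0.891 (SD, n = 3). Hug (FBgn0028374), which encodes the feeding-related peptide hugin, fell from 101 ± 12.2 to 13.8 ± 5.50 CPM. Transcripts of 2 genes with 0 counts in control appeared in FUS_WT: mthl8 (FBgn0052475, 3L, 22428 to 26308), a methuselah-like receptor gene, at 19.7 ± 0.197 CPM, at least 319-fold higher, and CG43050 (FBgn0262352, 2L, 13119294 to 13120767) at 17.1 ± 4.87 CPM, at least 277-fold higher. These bounds set control at the floor of 3 counts over the group. Orco (FBgn0037324), the coreceptor of odorant receptors, fell from 104 ± 17.0 to 20.3 ± 6.18 CPM.

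Other peptide genes that fell in FUS_WT were Capa (-1.10 ± 0.15, adjusted p = 0.00016) and AstA (-1.15 ± 0.22, 0.0048), and natalisin, a peptide gene outside the list, fell by 2.56 ± 0.24 on the log2 scale (1.5e-06). Of 23 neurotransmitter synthesis and transport genes 5 fell and 0 rose, among them the vesicular monoamine transporter Vmat (-1.09 ± 0.16, adjusted p = 0.00021) and the serotonin synthesis enzyme Trhn (-2.16 ± 0.34, 0.00081). Of 14 hemocyte (blood cell) markers 4 fell, including Hml (-1.32 ± 0.17) and the extracellular matrix gene Ppn (-1.06 ± 0.15), and the prophenoloxidase PPO1 rose (0.99 ± 0.19, adjusted p = 0.0047). Among 84 cytosolic ribosomal protein genes RpL32 rose from 834 ± 211 to 1668 ± 334 CPM (adjusted p = 0.0031) and 83 did not pass, with a list median of 0.32, and with an offset for gene length 6 rose and 0 fell. Among 23 nutrient and insulin responsive genes 4 rose and 2 fell: the translation repressor Thor (1.04 ± 0.18) and the gluconeogenesis enzyme Pepck2 (3.34 ± 0.55, or 4.33 without control replicate 1) rose, while Ilp2 and ImpL2, a secreted binder of insulin-like peptides, fell (ImpL2 -1.65 ± 0.21, adjusted p = 6.4e-05). Of 72 cytochrome P450 genes 6 rose and 4 fell, with Cyp28d2 at 2.48 ± 0.40, Cyp28a5 at -0.95 ± 0.15 and Cyp6g2 at -2.59 ± 0.38. The glutathione S-transferase GstT3 rose from 8.07 ± 1.73 to 25.7 ± 4.84 CPM (adjusted p = 0.00017). Of 30 photoreceptor markers 1 rose, the blue opsin Rh5 (1.04 ± 0.15, adjusted p = 0.00020), and 1 fell. Of 19 eye pigment genes 1 rose and 3 fell, among them the pigment transporter brown (bw, -1.02 ± 0.18, 0.0019). CG11313 (8.20 ± 0.38), CG15617 (6.51 ± 0.48) and CG6280 (5.26 ± 0.45) were also near absent in control, at 0.186 ± 0.162, 0.273 ± 0.237 and 0.407 ± 0.334 CPM, and without control replicate 3 the log2 fold change of CG15617, FUS_WT versus control, was 5.92 and that of CG6280 6.13. The odorant receptor Or59b (FBgn0034865) went from 11.7 ± 4.02 CPM in control to 0 counts in FUS_WT, at least 187-fold lower.

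None of the 45 DNA damage response and repair genes, the 22 DEAD-box RNA helicases or the 19 FUS and ALS gene orthologs passed in FUS_WT against control by edgeR over all genes. Adjusted over the list alone the counts were 0, 0 and 2, and the list tests gave adjusted p = 0.95, 0.69 and 0.72.

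In total 355 genes changed, 213 higher and 142 lower, and 1529 had an unadjusted p under 0.05. At least 2-fold changes were found for 160 higher and 70 lower genes, and 22.7% of genes had groups that did not overlap in CPM, where chance gives 10%. The count fell to 165 without FUS_WT replicate 2, 198 without control replicate 2 and 236 without control replicate 1, and was 615 in DESeq2 and 577 in limma-voom with quality weights. By camera, limma's test of a list against the other genes, 5 of 35 lists shifted in FUS_WT: neuropeptides down (adjusted p = 2.3e-09, and adjusted p = 0.42 with an estimated correlation, 14 of 30 adjusted over the list alone), ribosomal proteins up (2.3e-05, adjusted p = 0.94 with an estimated correlation, 1 of 84), hemocyte markers down (0.012, adjusted p = 0.42 with an estimated correlation, 7 of 14), neurotransmitter genes down (0.036, adjusted p = 0.56 with an estimated correlation, 8 of 23) and cuticle and trachea genes down (0.036, adjusted p = 0.74 with an estimated correlation, 2 of 32). The ribosomal call ended without FUS_WT replicate 3 (adjusted p = 0.16), the neurotransmitter call without FUS_WT replicate 3 (0.17), control replicate 2 (0.051) or FUS_R521C replicate 1 (0.056) and with an offset for gene length (0.086), and the cuticle call without control replicate 1 (0.095), control replicate 2 (0.11), FUS_WT replicate 1 (0.071) or FUS_WT replicate 2 (0.095) and with no scaling beyond library size (0.056). Without all 3 replicate 3 libraries the ribosomal (0.19), neurotransmitter (0.27) and hemocyte (0.063) calls ended, and by fry the ribosomal (0.34) and cuticle (0.22) lists did not pass. The nutrient (adjusted p = 0.71; 8 of 23 adjusted over the list alone), P450 (0.75; 14 of 72), glutathione S-transferase (0.11; 6 of 32), photoreceptor (0.69; 4 of 30) and eye pigment (0.075; 4 of 19) lists did not pass. By fry the eye pigment list passed (adjusted p = 0.038).

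**Figure D2:**
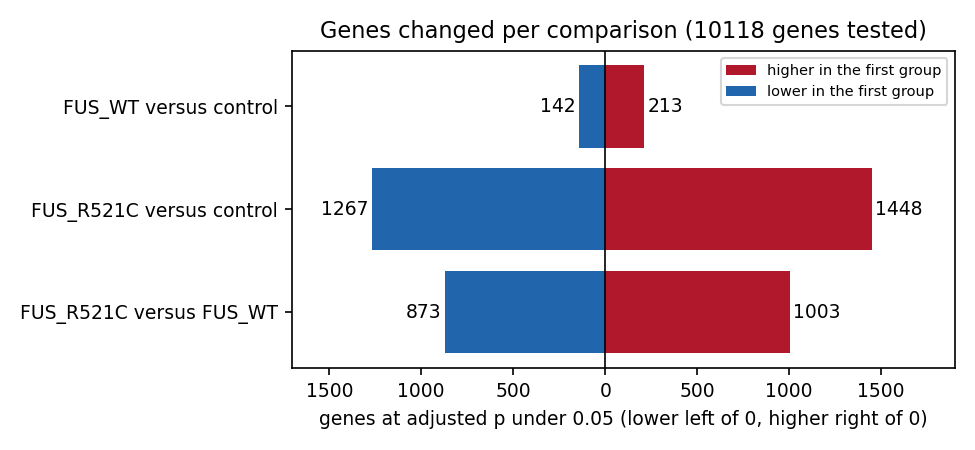
Number of genes at adjusted p under 0.05 in each comparison (edgeR, 10118 genes tested), with genes higher in the first group drawn right of 0 and genes lower in it drawn left of 0. FUS_R521C against control gave 1448 higher and 1267 lower genes, and FUS_WT against control 213 and 142.

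FUS_R521C against control compares flies with the ALS-linked form to the control, and line and FUS are confounded here too. Of 84 ribosomal protein genes 55 were higher, 0 lower and 29 did not pass, with a median log2 fold change of 0.89 (list adjusted p = 3.4e-12, and adjusted p = 0.79 with an estimated correlation). The counts were 58 higher and 4 lower adjusted over the list alone, 52 and 4 with no scaling beyond library size, and 48 and 7 with an offset for gene length. RpL32 (FBgn0002626, 3R, 30045229 to 30046161) went from 834 ± 211 to 5915 ± 440 CPM (SD, n = 3). Of 25 synaptic vesicle and active zone genes 14 fell, 2 rose and 9 did not pass, with adjusted p = 0.83 with an estimated correlation and, with the offset for gene length, adjusted p = 0.33 and a mean of -0.22 in place of -0.49. Of 30 photoreceptor markers 17 fell, 1 rose and 12 did not pass (adjusted p = 0.42 with an estimated correlation). The vesicle priming factor unc-13 (FBgn0025726, chromosome 4, 867824 to 912331) fell from 522 ± 55.7 to 205 ± 43.4 CPM (log2 fold change -1.35 ± 0.18, or -0.70 with the offset for gene length). The eye-enriched G protein subunit Ggamma30A (FBgn0267252, 2L, 9256563 to 9302494) fell from 6561 ± 1384 to 2175 ± 353 CPM.

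Among other synaptic genes, the sodium channel para, at 325 ± 70.8 CPM in control, fell (adjusted p = 0.00013), by a log2 fold change of -0.89 with the offset for gene length, and the calcium channel cac fell by 1.15 ± 0.18 on the log2 scale (0.00014; -0.62 with the offset). Of the photoreceptor markers, the sodium-calcium exchanger Calx fell by 1.23 ± 0.17. Of 23 neurotransmitter genes 13 fell and 1 rose. Among those that fell were Vmat at -1.24 ± 0.16, the serotonin transporter SerT at -1.66 ± 0.22 and the tyramine synthesis enzyme Tdc2 at -2.45 ± 0.42, while Hn, phenylalanine hydroxylase, rose by 1.06 ± 0.14. Neuropeptide genes went both ways: 4 of 30 rose, among them NPF (1.73 ± 0.25), and 11 fell, among them Hug (-1.37 ± 0.24). Pan-neuronal markers did too, with CadN (-1.22 ± 0.20, or -0.61 with the offset for gene length) and Appl (-0.73 ± 0.15) lower, elav higher (0.76 ± 0.18) and 8 of 11 not passing. Of 31 splicing and hnRNP factors 12 fell and 2 rose. Psi, an RNA-binding splicing regulator, fell by 1.23 ± 0.18. Among 15 circadian clock genes 4 fell and 0 rose, with tim at -1.01 ± 0.20. With no scaling beyond library size the counts higher and lower were 1 and 16 for neurotransmitter genes, 2 and 13 for neuropeptides, 1 and 5 for pan-neuronal markers, 1 and 15 for splicing factors and 0 and 8 for clock genes.

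Several genes of detoxification and defence rose. Of 72 cytochrome P450 genes 21 rose and 8 fell, with Cyp4d1 up from 22.4 ± 4.61 to 190 ± 18.8 CPM, Cyp304a1 by 4.64 ± 0.32 and Cyp9h1 by 3.14 ± 0.22 on the log2 scale. Of 32 glutathione S-transferases 9 rose, including GstT3 (2.37 ± 0.23), and 2 fell, including GstE4 (-3.95 ± 0.59). Of 28 Imd and Toll pathway components 8 rose and 0 fell, among them the pattern recognition genes GNBP3 (1.24 ± 0.16) and GNBP1 (1.39 ± 0.24). Of 17 antimicrobial peptide genes 3 rose and 0 fell, or 3 and 1 with no scaling beyond library size, and the list did not pass by camera (adjusted p = 0.19). Of 11 JAK/STAT and Turandot genes 3 rose, led by TotX (2.94 ± 0.60). Of 20 antioxidant genes 5 rose and 2 fell, with the ferritin subunit Fer2LCH up from 413 ± 12.4 to 1376 ± 128 CPM and the metallothionein MtnA up by 1.26 ± 0.18. Hemocyte markers split, with PPO1 (2.25 ± 0.20) and NimC4 (2.37 ± 0.26) among the 5 of 14 that rose and Hml (-1.89 ± 0.17) among the 4 that fell. Of 69 nuclear-encoded respiratory chain genes 23 rose, such as ND-B18 (1.82 ± 0.18) and ATPsynD (1.44 ± 0.19), and 4 fell. With no scaling beyond library size 19 rose and 9 fell, and with an offset for gene length 18 rose and 17 fell, while the list mean went from 0.35 to 0.02. Proteasome subunits gave 9 higher and 0 lower of 31, but 7 higher and 8 lower with no scaling beyond library size, with Prosbeta6 at 1.07 ± 0.19. In the unfolded protein and integrated stress response list 6 rose and 3 fell of 20, and the chaperone Hsc70-3 (BiP) rose by 0.96 ± 0.17. Of 23 nutrient responsive genes 9 rose, with Thor at 1.29 ± 0.18 and Pepck2 at 3.42 ± 0.55 (4.41 without control replicate 1), and 5 fell, with ImpL2 at -2.21 ± 0.21. With no scaling beyond library size the P450 list gave 18 higher and 15 lower, glutathione S-transferases 7 and 4, Imd and Toll components 5 and 2, JAK/STAT genes 2 and 0, antioxidant genes 4 and 5, hemocyte markers 4 and 5, the unfolded protein list 4 and 4, and nutrient responsive genes 6 and 6. RpS3A, on chromosome 4, rose by 2.05 ± 0.18 among the ribosomal protein genes.

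Of 45 DNA damage response and repair genes 4 passed in FUS_R521C. The photolyase gene phr rose (1.59 ± 0.27, adjusted p = 0.00026), as did mus304, the ATRIP ortholog (1.92 ± 0.59, 0.022), and the helicase gene Blm (-1.71 ± 0.38, 0.0024) and DNAlig3 (-0.69 ± 0.21, 0.022) fell. Mus304 did not pass without control replicate 1 (0.084), control replicate 3 (0.060) or FUS_R521C replicate 1 (0.055), and DNAlig3 did not without control replicate 1 (0.13), control replicate 3 (0.059) or FUS_R521C replicate 2 (0.069). As a list the repair genes did not pass (median 0.0030, or -0.19 with no scaling beyond library size and -0.0059 with DESeq2's size factors, adjusted p = 0.75; 2 of 45 adjusted over the list alone). Of 22 DEAD-box helicases 2 rose and 5 fell, with pths at -1.12 ± 0.20 (list adjusted p = 0.35; 7 adjusted over the list alone). Of 19 FUS and ALS gene orthologs 2 rose, with the profilin gene chic at 0.84 ± 0.17, and 5 fell, with Fmr1 at -0.98 ± 0.20 beside caz. That list had adjusted p = 0.27 by camera and 0.0047 by fry, and 9 members passed adjusted over the list alone. With no scaling beyond library size 0 helicases were higher and 7 lower, and 1 ortholog was higher and 7 lower.

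The largest single changes included sordd2 (FBgn0052581, X, 15796908 to 15799162), absent in control and at 24.5 ± 2.82 CPM in FUS_R521C, at least 397-fold higher. Genes high in FUS_WT were high here too, with mthl8 at 28.7 ± 10.4 CPM (at least 464-fold above control), CG43050 at 10.9 ± 5.34 CPM (at least 177-fold) and CG11313 at 80.6 ± 12.0 CPM. The peptide gene CNMa fell by 4.03 ± 0.48 and Orco by 2.51 ± 0.27 on the log2 scale (adjusted p = 6.2e-06 and 6.6e-06).

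Between FUS_R521C and control 2715 genes changed, 1448 higher and 1267 lower, and 3857 had an unadjusted p under 0.05. Of these, 709 rose and 375 fell at least 2-fold, and 42.0% of genes had groups that did not overlap in CPM (chance 10%). The split depends on scaling: with no scaling beyond library size the median of all genes moves to -0.21 and the higher genes from 53.3% to 31.5% of the calls. By camera 7 of 35 lists shifted. Ribosomal proteins rose (adjusted p = 3.4e-12, and adjusted p = 0.79 with an estimated correlation, 62 of 84 adjusted over the list alone), as did respiratory chain genes (0.021, adjusted p = 0.94 with an estimated correlation, 30 of 69), JAK/STAT genes (0.036, adjusted p = 0.56 with an estimated correlation, 6 of 11) and P450 genes (0.036, adjusted p = 0.56 with an estimated correlation, 37 of 72). Photoreceptor markers fell (0.00029, adjusted p = 0.42 with an estimated correlation, 20 of 30), as did synaptic genes (0.00091, adjusted p = 0.83 with an estimated correlation, 17 of 25) and neurotransmitter genes (0.0026, adjusted p = 0.42 with an estimated correlation, 14 of 23). With an offset for gene length the synaptic (adjusted p = 0.33), respiratory chain (0.90) and P450 (0.14) calls ended. The respiratory chain call also ended without FUS_R521C replicate 1 (0.17) and in fry (0.14), the JAK/STAT call without control replicate 2 (0.074), control replicate 3 (0.077) or FUS_R521C replicate 1 (0.056) and with a strict filter (0.056), and the P450 call without control replicate 1 (0.079), FUS_R521C replicate 1 (0.087) or FUS_R521C replicate 3 (0.069). Among lists described above that did not pass were circadian (adjusted p = 0.074; 4 of 15 adjusted over the list alone), splicing (0.11; 17 of 31), neuropeptide (0.11; 16 of 30), Imd and Toll (0.11; 8 of 28), pan-neuronal (0.16; 3 of 11) and unfolded protein (0.21; 11 of 20) genes. The proteasome (0.27; 9 of 31), glutathione S-transferase (0.51; 11 of 32), nutrient (0.68; 15 of 23), antioxidant (0.69; 8 of 20) and hemocyte (0.98; 10 of 14) lists did not pass either. By fry the circadian (adjusted p = 0.0031), splicing (0.0052) and Imd and Toll (0.043) lists passed, and the rest of these lists did not.

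**Figure D3:**
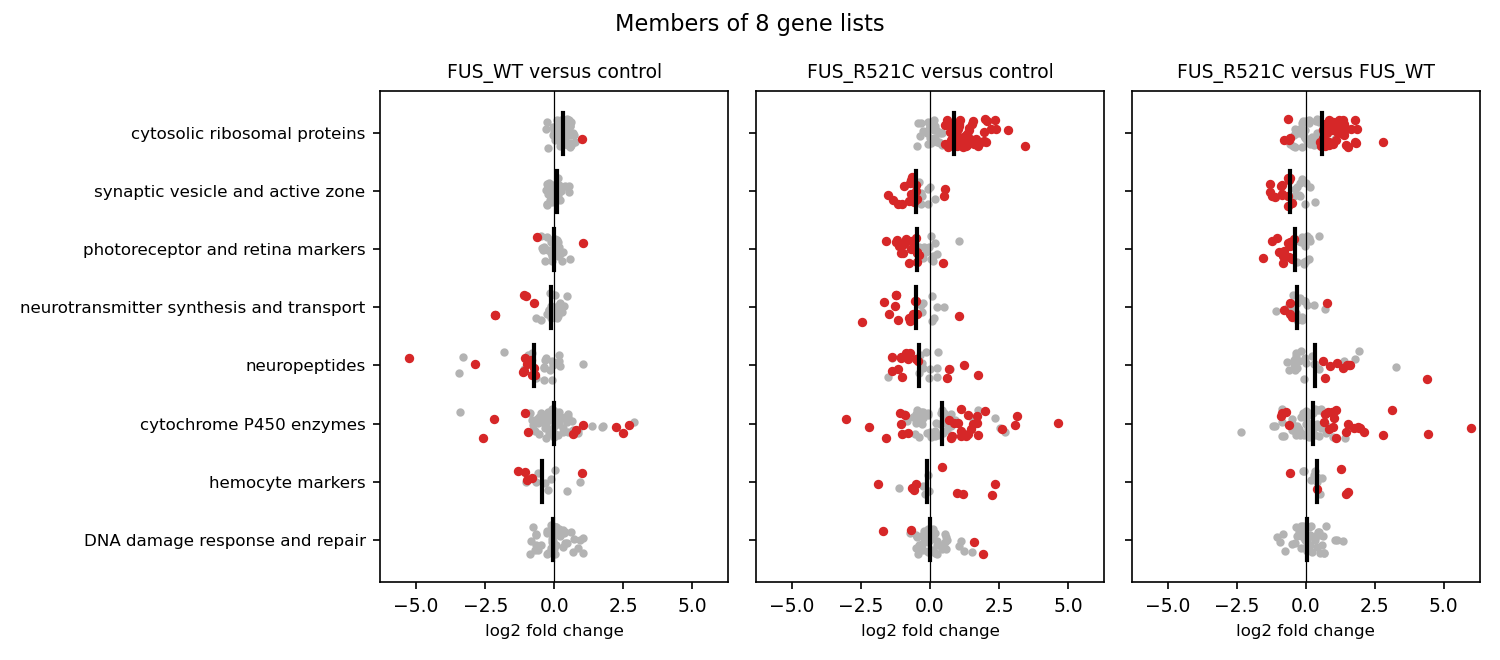
Log2 fold change (x axis) of each tested member of 8 gene lists in the 3 comparisons, drawn at 6 or -6 where larger; red points have adjusted p under 0.05, grey points do not, and a black bar marks the list median. The ribosomal median is 0.32, 0.89 and 0.60 in the 3 panels and the neuropeptide median -0.72, -0.38 and 0.33; the DNA repair median lies within 0.1 of 0 in each panel and, with no scaling beyond library size, is -0.19 in the second and -0.07 in the third.

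FUS_R521C against FUS_WT compares both FUS groups directly. Line and the level of FUS, which was not analysed, may differ too and cannot be told apart from the form. Ilp2 was higher in FUS_R521C (33.1 ± 11.5 against 1.59 ± 0.891 CPM, SD, n = 3; log2 fold change 4.38 ± 0.36, adjusted p = 9.7e-07), and 9 of 30 neuropeptide genes were higher and 0 lower. The gene sordd2 had 0 counts in FUS_WT and was at least 390.0-fold higher in FUS_R521C. Ribosomal protein genes were higher (39 of 84, with 4 lower) and synaptic genes lower (14 of 25, with 0 higher). With an offset for gene length the ribosomal genes gave 33 higher and 14 lower, with 49.5% of the list mean kept (0.29 of 0.58), and the synaptic genes 0 higher and 10 lower, with 55.1% kept. The mitochondrially encoded mt:CoIII (FBgn0013676, mitochondrial genome, 4736 to 5524), a cytochrome oxidase subunit, was at 7446 ± 1370.2 CPM against 911 ± 324 (3.03 ± 0.26, adjusted p = 7.0e-06). The other mitochondrially encoded oxidase subunits did not pass (-0.04 ± 0.49, adjusted p = 0.97, and -0.29 ± 0.44, 0.73).

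Further peptide genes higher in FUS_R521C than in FUS_WT were Ms (1.34 ± 0.17), Crz (1.62 ± 0.21) and NPF (1.57 ± 0.25). RpL32 (1.83 ± 0.19) and RpS3A (1.66 ± 0.17) were higher, as were the respiratory chain genes ND-B18 (1.61 ± 0.18) and COX6B (1.46 ± 0.22) among 24 higher and 2 lower of 69 (19 and 7 with an offset for gene length, where the list mean was -0.01). Proteasome subunits gave 10 higher and 1 lower of 31 (7 and 2 with no scaling beyond library size), with Prosbeta7 at 96.9 ± 13.7 against 48.6 ± 6.44 CPM and Rpt2 at 1.03 ± 0.17. Of the synaptic genes, cac fell by 1.30 ± 0.18, the t-SNARE Syx1A by 1.29 ± 0.19 and unc-13 by 1.10 ± 0.18 on the log2 scale (cac -0.83 and unc-13 -0.50 with the offset for gene length). Of 30 photoreceptor markers 15 were lower and 0 higher, with Ggamma30A at -1.54 ± 0.17, the phospholipase norpA at -1.20 ± 0.16 and rdgB at -1.03 ± 0.17. Of 11 pan-neuronal markers 6 were lower, including CadN (-0.96 ± 0.20, or -0.43 with that offset). P450 genes gave 20 higher and 4 lower of 72, with Cyp4d1 at 2.78 ± 0.18 and Cyp304a1 at 4.43 ± 0.32, and glutathione S-transferases 9 higher and 1 lower of 32, with GstE6 at 1.68 ± 0.18 and GstD1 at 1.08 ± 0.18. The melanisation enzymes PPO1 (1.26 ± 0.19) and PPO2 (1.53 ± 0.18) and NimC4 (1.46 ± 0.25) were among 4 higher and 1 lower of 14 hemocyte markers. Among 28 Imd and Toll components 8 were higher and 0 lower, with PGRP-LF at 2.36 ± 0.40. With no scaling beyond library size this list gave 5 higher and 1 lower, and neuropeptides 8 and 2. The sugar-responsive glycosidase gene tobi was at 2.92 ± 0.42 (2.27 without FUS_R521C replicate 2). Of 31 splicing factors 11 were lower, with Psi at -1.12 ± 0.18 and pAbp at -0.77 ± 0.16, and 3 higher, with U2af38 at 1.12 ± 0.18. Genes lower in FUS_R521C included mei-W68, the meiotic SPO11 ortholog (-2.28 ± 0.43), and CG6421 (-2.22 ± 0.25). Of 45 DNA repair genes 0 passed in edgeR over all genes, and 0 adjusted over the list alone (list adjusted p = 0.71), while 0 were higher and 3 lower with no scaling beyond library size. Of 22 DEAD-box helicases 2 were higher and 2 lower (list adjusted p = 0.11 by camera and 0.099 by fry). Of 19 FUS and ALS gene orthologs 2 were higher and 3 lower (0.084 by camera and 0.0031 by fry). With no scaling beyond library size 1 helicase was higher and 8 lower, and 0 orthologs were higher and 6 lower.

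In this comparison 1876 genes changed, 1003 higher and 873 lower, 423 and 189 of them at least 2-fold, and 3158 had an unadjusted p under 0.05. Groups did not overlap in CPM for 34.2% of genes (chance 10%). With no scaling beyond library size the all-gene median moves to -0.18 and the higher genes from 53.5% to 32.8% of the calls. The count fell to 1051 without FUS_WT replicate 2, 1138 without FUS_WT replicate 1 and 1207 without FUS_R521C replicate 3, and was 1146 at a minimum fold of 1.2. By camera 11 of 35 lists shifted. Those lower in FUS_R521C were synaptic genes (adjusted p = 3.4e-05, and adjusted p = 0.74 with an estimated correlation, 15 of 25 adjusted over the list alone), photoreceptor markers (8.9e-05, adjusted p = 0.42 with an estimated correlation, 15 of 30) and pan-neuronal markers (0.0035, adjusted p = 0.75 with an estimated correlation, 7 of 11). Those higher were ribosomal proteins (1.8e-08, adjusted p = 0.83 with an estimated correlation, 52 of 84), respiratory chain genes (0.00011, adjusted p = 0.86 with an estimated correlation, 30 of 69), P450 genes (0.0053, adjusted p = 0.52 with an estimated correlation, 27 of 72), hemocyte markers (0.0082, adjusted p = 0.42 with an estimated correlation, 7 of 14) and neuropeptides (0.017, adjusted p = 0.75 with an estimated correlation, 11 of 30). Proteasome subunits (0.023, adjusted p = 0.92 with an estimated correlation, 13 of 31), glutathione S-transferases (0.036, adjusted p = 0.83 with an estimated correlation, 12 of 32) and JAK/STAT genes (0.036, adjusted p = 0.56 with an estimated correlation, 2 of 11) were higher as well. With the offset for gene length the calls of synaptic genes (adjusted p = 0.059), respiratory chain genes (0.17), pan-neuronal markers (0.73), P450 genes (0.054), neuropeptides (0.31), proteasome subunits (0.64) and glutathione S-transferases (0.42) ended. The neuropeptide call also ended without FUS_R521C replicate 1 (0.065), the JAK/STAT call without FUS_WT replicate 1 (0.088) or FUS_R521C replicate 1 (0.052) and with a strict filter (0.093), and the proteasome call without FUS_WT replicate 2 (0.074), FUS_R521C replicate 1 (0.078) or FUS_R521C replicate 3 (0.069) and with no scaling beyond library size (0.056). The hemocyte call ended without all 3 replicate 3 libraries (0.071). By fry the ribosomal (0.080), respiratory chain (0.090), proteasome (0.12) and glutathione S-transferase (0.078) lists did not pass. The glutathione S-transferase call ended without control replicate 1 (0.059), control replicate 2 (0.059), FUS_WT replicate 1 (0.13), FUS_WT replicate 2 (0.095), FUS_R521C replicate 1 (0.12) or FUS_R521C replicate 3 (0.12). The splicing (adjusted p = 0.074; 18 of 31 adjusted over the list alone) and Imd and Toll (0.079; 8 of 28) lists did not pass, though the latter did without FUS_WT replicate 3 (0.017). By fry the splicing list passed (adjusted p = 0.0084) and the Imd and Toll list did not (0.080).

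**Figure D4:**
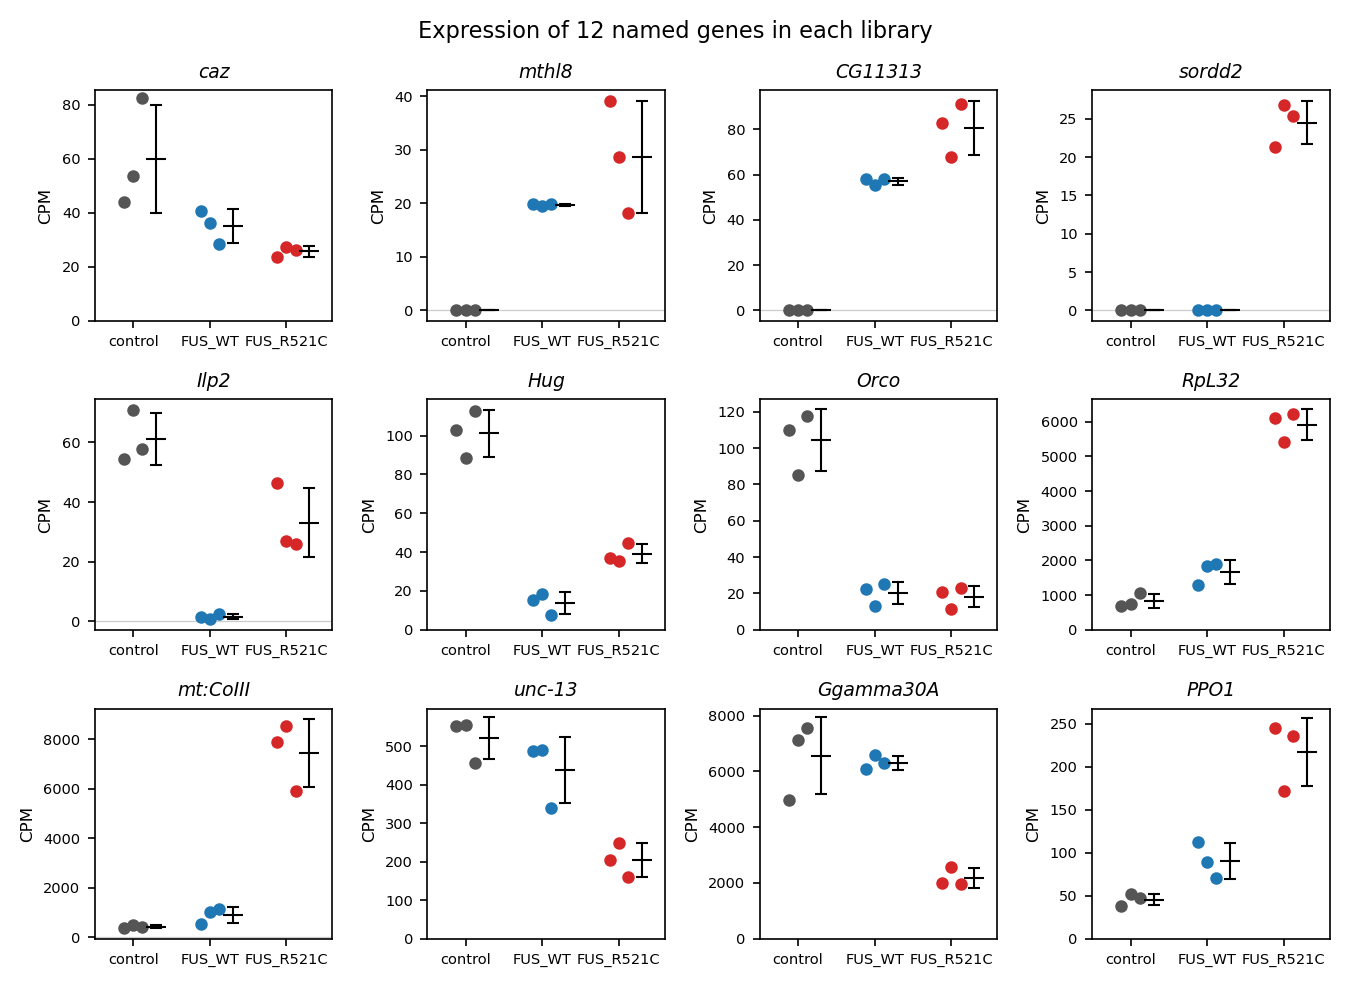
CPM (y axis, linear) of 12 named genes in each of the 9 libraries by group (x axis), with dots for libraries and a bar for the mean ± SD of n = 3. Ilp2 falls from 61.1 CPM in control to 1.59 in FUS_WT and lies at 33.1 in FUS_R521C; RpL32 lies at 834, 1668 and 5915 CPM.

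Both FUS groups were also set beside each other through the shared control. Of the genes called against control in either group, 284 changed the same way in both, 191 higher and 93 lower, and 6 changed in opposite directions. In 20 simulations all 9 libraries, controls included, were drawn anew around the control means with no gene changed. Both simulated FUS groups then shared a median of 0 and at most 1 gene, as no change was built in. Independent lists of these sizes would share 30.5 higher and 17.8 lower genes. Across genes, which are not independent replicates, the log2 fold changes had r = 0.664 and a covariance of 0.810, against 0.490 and 0.145 in the simulation, a difference in covariance of 0.665. The same sign was found for 66.6% of genes and for 66.9% in the simulation. With only 3 controls they could not be divided between both comparisons, so part of the excess of shared genes over independent lists may come from the shared controls. The difference in covariance leaves out only what shared controls add on average in the simulation. Deviations of the real controls, the trend with gene length and correlations between libraries of different groups were not simulated. The count of 284 fell to 144 without FUS_WT replicate 2, 164 without control replicate 2 and 184 without control replicate 1, and was 446 in DESeq2. A test over all 3 groups found 2693 genes that differed.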

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

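The tests of strain background, of nervous tissue share and of antennal tissue were chosen after the results were seen, and the length offset was added after the data were examined.

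Both FUS groups differed from each other in several genes by a direct test. Ilp2 was higher in FUS_R521C than in FUS_WT by a log2 fold change of 4.38, 9 neuropeptide genes were higher in FUS_R521C, and sordd2 was at least 390.0-fold higher. In 6 genes the sign against control was opposite, lower in FUS_WT and higher in FUS_R521C, with the difference tested directly. They are Ms, the peptide myosuppressin (-0.73 and 0.61, adjusted p of the difference 2.9e-05), CG32444 (-0.79 and 1.54, 1.3e-07), CG8586 (-0.85 and 1.36, 5.6e-08), Hao (-1.18 and 1.15, 2.1e-06), Echs1 (-0.81 and 0.91, 9.7e-07) and hpRNA:CR18854 (-0.61 and 0.80, 4.2e-06). These 6 were chosen after their values were seen, for opposite calls against the same control. A small p of the difference follows from that choice and adds no separate evidence. CG8586 and Echs1 kept both calls in the alternatives run. Without control replicate 2 the FUS_WT calls of Ms (0.078), CG32444 (0.13) and hpRNA:CR18854 (0.080) did not pass. The same holds without FUS_WT replicate 2 (0.093, 0.065 and 0.11), for Ms and hpRNA:CR18854 without control replicate 3 (0.10 and 0.14), for CG32444 and hpRNA:CR18854 without FUS_WT replicate 1 (0.061 and 0.075), and for Ms without FUS_WT replicate 3 (0.062). The FUS_R521C call of Ms did not pass without control replicate 1 (0.077).

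Against control 55 of 84 ribosomal protein genes, which are short (median 921.5 bp against 2090 bp for all genes), rose in FUS_R521C and 0 fell. Of 25 synaptic genes, which are long (median 5803 bp), 14 fell, 2 rose and 9 did not pass. With the length offset the ribosomal list was still called (adjusted p = 1.2e-07, mean 0.55, SD 0.78, against 0.90, SD 0.77), which argues against a length trend as the whole source there, though without the offset adjusted p = 0.79 with an estimated correlation, and against FUS_WT only 49.5% of the mean was kept, so a length trend as the main source stays open for that comparison. The synaptic call ended with the offset (adjusted p = 0.33, mean -0.22, SD 0.44, against -0.49, SD 0.51) because the fold shrank. A length trend between libraries may account for it, though the offset also removes biology that goes with length. Without the offset the synaptic list had adjusted p = 0.83 with an estimated correlation. Against control, the 11 pan-neuronal markers moved apart with the offset (Cochran's Q = 113, probability 1.3e-19). Elav and fne were higher and Appl and CadN lower, though fne is higher only with the offset (0.42) and changes sign between settings. Without the offset 1 marker was higher, 2 lower and 8 did not pass. Changes of single genes on top of a lower share of nervous tissue would also move the markers apart. The offset can also remove a common fall of long genes, so the test does not decide and a lower share stays open. Against FUS_WT 6 of the 11 markers were lower and 0 higher (adjusted p = 0.0035). That list had adjusted p = 0.75 with an estimated correlation and 0.73 with the length offset, so a lower share stays open there too. An effect of the R521C protein on these genes stays open and was not tested apart from the groups.

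A set of 18 genes was under 1 CPM in each control and at 3 CPM or more in each FUS library, among them mthl8, CG43050, CG11313, CG15617 and CG6280. Linkage to 1 inserted transgene is argued against by their positions: at most 2 lie within 2 Mb, and 0.997 of random draws hold as many. Of the 84 splits of the 9 libraries into 3 and 6, only 1, the real one, gave 18 genes, and the highest other gave 4, which argues against chance. A strain background that both FUS lines share and the control lacks may be the source and cannot be told apart from an effect of FUS, because line and FUS are confounded. Only 1 of the 18 genes, asRNA:CR45171, named after its value was seen, differs between FUS_R521C and FUS_WT, but the genes were chosen for being present in both, so this decides nothing.

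Of 41 chemoreceptor genes, 6 were lower and 2 higher in FUS_WT, and 10 lower and 2 higher in FUS_R521C. Less antennal tissue in the FUS samples could lower them. In FUS_WT 0 of 10 antennal support genes passed, with a mean log2 CPM difference of -0.02 (SD 0.54) against -0.97 (SD 1.95) for the receptors. The difference between the lists was 2.73 standard errors. These standard errors run across genes, which are not independent replicates, and leave out the spread between libraries. The test therefore does not decide, and less antennal tissue stays open there. In FUS_R521C the difference was 1.51 standard errors, too little to decide, and less antennal tissue cannot be told apart from a change in receptor genes. The test was first run over both FUS groups as 1 pattern, where it did not decide, and was divided by group after those values were seen.

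Splits of the 6 libraries of a comparison are too few to reach a share under 0.05. In FUS_WT against control 1 of 10 splits, the real one, gave 355 genes and the highest other 0. For FUS_R521C against control it was 1 of 10, with 2715 and 0, and for FUS_R521C against FUS_WT 1 of 10, with 1876 and 1. For the test over all 3 groups 1 of 100 drawn from 280 splits gave 2693, and the highest other gave 1648, which argues against chance. A split that keeps 1 real group together retains part of the real difference, so 1648 need not point to other structure among the samples.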

How the results depend on the processing

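The length offset and leaving out the replicate 3 libraries were chosen after the data were seen; the other alternatives were planned. The cause was not tested where none is given.

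Genes changed in FUS_WT against control numbered 615 with DESeq2, 577 with quality weights, 231 without the replicate 3 libraries (fewer samples) and 165 to 406 when 1 library was left out. Those in FUS_R521C against FUS_WT numbered 1146 at a minimum fold of 1.2, a stricter test by construction, and 1051 to 1889 when 1 library was left out. Genes changed the same way in both FUS groups numbered 446 with DESeq2, 160 without the replicate 3 libraries and 144 to 297 when 1 was left out. FUS_R521C against control stayed between 1930 and 2801 and the test over all groups between 1955 and 2813 when 1 library was left out.

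With an estimated correlation 0 lists shifted in FUS_WT against control, 0 in FUS_R521C against control and 0 in FUS_R521C against FUS_WT. Fry called 12 lists in FUS_R521C against control, and the length offset left 4 in FUS_R521C against FUS_WT. When 1 library was left out the lists ran from 3 to 9, from 5 to 8 and from 7 to 14.

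The log2 fold change of Rm62, FUS_WT versus control, reversed with no scaling beyond library size (-0.0035) and ran from -0.0233 to 0.1052 when 1 library was left out. Its other changes passed with no scaling beyond library size (adjusted p = 0.0094 against control and 0.014 against FUS_WT), where the median of all genes also moved down, and in DESeq2 (0.026 and 0.019). The log2 fold change of fne, FUS_R521C versus control, was reversed by the length offset (0.42, from below 0) and ran from -0.1241 to 0.0327 when 1 library was left out. Caz in FUS_WT passed with no filter (0.017) and in DESeq2 (0.025).

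A replicate block gave 323, 2572 and 1776 genes, and the numbers are not shown by the labels to pair samples. Deviations from the group mean correlated positively between libraries numbered 2 (0.32, 0.16 and 0.22) and between those numbered 3 (0.36, 0.34 and 0.18), but not between those numbered 1 (-0.02, 0.04 and -0.08), and were negative between numbers 2 and 3 (down to -0.44). These deviations sum to 0 within a group, so a feature shared by the libraries of 1 number also moves the others. The values therefore do not tell whether libraries numbered 2, those numbered 3 or both share something across groups. Not every library correlates best with its own number (control 1 with FUS_WT 2 at 0.25).

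Few 1.5-fold changes were found in the simulations, where 2%, 6% and 4% were recovered with 50 genes changed at each fold. The adjusted threshold is looser where many genes change, so these shares may be too low for the comparisons with FUS_R521C.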

Other observations

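The tests named in this part were chosen after the results were seen.

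In the mitochondrial genome mt:ATPase6 (4062 to 4736) and the adjoining mt:CoIII (4736 to 5524) were higher in FUS_R521C than in control, at 1286 ± 495 against 206 ± 13.6 CPM (SD, n = 3; log2 fold change 2.64 ± 0.35, adjusted p = 0.00065) and 7446 against 433 ± 72.4 CPM (4.10 ± 0.28, adjusted p = 3.7e-07). Changes of mt:ND4 (1.62 ± 0.54, adjusted p = 0.065), mt:ND5 (1.56 ± 0.52, 0.060) and mt:Cyt-b (1.02 ± 0.34, 0.055) did not pass but did in DESeq2 (0.013, 0.0013 and 0.028), without FUS_WT replicate 2 (0.031, 0.037 and 0.021) and without FUS_R521C replicate 3 (0.025, 0.0011 and 0.0083), and that of mt:Cyt-b also without control replicate 3 (0.037). Further genes did not pass and went both ways, with mt:CoI at 0.66 ± 0.50 (adjusted p = 0.39) and mt:CoII at 0.49 ± 0.44 (0.47, and 0.014 without the replicate 3 libraries). Among those below 0, the gene at 3907 to 4068, which overlaps mt:ATPase6, was at -0.23 ± 0.48 (adjusted p = 0.78). The large ribosomal RNA at 12735 to 14058 was at -0.54 ± 0.50 (0.49). In FUS_WT against control mt:CoIII was higher too (1.07 ± 0.25, 0.030), a call lost without control replicate 1 (0.14), control replicate 3 (0.11), FUS_WT replicate 2 (0.14), FUS_WT replicate 3 (0.090), FUS_R521C replicate 1 (0.078) or FUS_R521C replicate 2 (0.051). These genes were chosen after their values were seen.

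Ilp2 was lower than control in FUS_R521C as well (-0.88 ± 0.30, adjusted p = 0.038), a change chosen after its value was seen. It did not pass without control replicate 1 (0.061), control replicate 2 (0.13), control replicate 3 (0.066), FUS_WT replicate 1 (0.062), FUS_R521C replicate 2 (0.14) or FUS_R521C replicate 3 (0.14).

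The 18 genes near absent in control lie on 2L (3), 2R (4), 3L (6) and 3R (5), with 0 on X, where 16.5% of tested genes lie (p of none 0.038). Besides these, 3 genes, Or92a, CG15539 and Or59b, show the converse. Of the 18 genes 4 overlap another annotated gene. The call of asRNA:CR45171 between FUS_R521C and FUS_WT did not pass without FUS_WT replicate 1 (0.24), FUS_WT replicate 2 (0.18), FUS_R521C replicate 1 (0.081), FUS_R521C replicate 2 (0.12) or FUS_R521C replicate 3 (0.11).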
